A study of Mus musculus with 12 samples.

How the data were processed

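Lineage-negative marrow cells of C57BL/6J mice were grown in serum-containing StemSpan medium with IL-3, SCF and FLT3 ligand, transduced for 24 h with the MigR1 vector alone or with MigR1 carrying tagged RUNX1-ETO, and then kept for a further 24 h without or with 10 ng/mL GM-CSF, per the labels' growth protocol. Sorted cells thus had 48 h of RUNX1-ETO expression. Total RNA was purified on columns and its quality examined on a Bioanalyzer, per the labels' extraction protocol, and was biotin-labelled and hybridized to Illumina Mouse Ref-8 v2.0 BeadChips, per the labels' labelling protocol. Sample groups and replicate numbers came from each sample's own title and description, and titles name the fusion AE where descriptions name it RE. All 12 samples were placed in a group, and 0 columns of values were left unused.

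The main table holds bead-summarized signal intensity on a linear scale, as deposited before normalization, with no detection p-values; all values were positive, so that the optical background was still in them. Its summarization software is not given in the sources used here. A further table holds intensity that the authors normalized between arrays by a method that is not given in the sources used here. From the values, each of its columns ranked the probes of its array as the deposited unnormalized table did (rank correlation 1), and Mig+GM replicate 2 equalled its unnormalized values within 0.005. The medians of that normalized table were 80.1, 79.7 and 80.7 for Mig, 78.6, 79.1 and 79.9 for Mig+GM, 78.6, 78.4 and 80.1 for RE, and 79.8, 78.6 and 79.6 for RE+GM, replicates 1 to 3. The unnormalized signals were the basis of every main value, and the normalized ones an alternative.

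Signals were background-corrected with normexp, with an offset of 50 added, quantile-normalized and put on the log2 scale in limma 3.58.1 (R 4.3.3). The offset steadies dim probes and makes fold changes smaller than signals alone would give. The array holds 25697 probes, of which 23978 have 1 gene in the annotation used, 0 have several and 1719 are not listed in it; 23962 gene identifiers were matched, 0 symbols were updated, and 16593 genes were on the array. The plan was to keep probes with a detection p under 0.05 on at least 3 of the 12 arrays. Because no detection p-values were in the tables, the background of each array was instead estimated from the lower flank of its own signals (its mode and the spread below it), and probes above it at p under 0.05 on at least 3 arrays were kept. That filter was chosen after the data had been seen. It kept 16388 probes. One unit was then tested per gene, its probe with the highest mean over all arrays, which gave 11142 genes (8206 with a single probe kept, 2936 with several) and 980 probes with no gene name. A probe measures 1 part of a transcript, and no named gene had another probe called in the opposite direction. Among genes named in the text another probe was not called where the tested one was for Egfl7, Adgre1, Ermap, Csf2rb, Egln3 and Runx1t1 without GM-CSF, for Pim1, Mcm4, Ifitm1, Egln3 and Runx1t1 with it, for Bcat1 with GM-CSF in Mig cells, for Nts, Egln3, Pim1, Itgb1 and Slc4a8 with GM-CSF in RE cells, and for Nts and Mmp13 in the interaction. No probe was named Kit in the annotation and Flt3 did not pass the filter, so neither was analysed here. Genome coordinates were not used here.

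A group-means model over all 12 arrays was fitted with limma's lmFit and eBayes, with two-sided tests and Benjamini-Hochberg adjustment over all 12122 units within each contrast, at 0.05. The contrasts were RE against Mig without and with GM-CSF, GM-CSF within Mig and within RE cells, and the interaction. Errors beside log2 changes are standard errors of the model. Where a gene was under background on all arrays of a group, its fold is given as a lower bound against that background. For the interaction such a group was put at its background or at the lowest value of its arrays, whichever made the difference smaller. A bound was also given for the tested Runx1t1 probe, although its other probe was above background on some control arrays. Where an array is named as above background, the estimate described above was used.

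Whether replicate numbers pair arrays across groups was checked after removing group means: arrays with the same number correlated across genes by 0.62, 0.61 and 0.69 between Mig and Mig+GM, 0.22, 0.12 and 0.47 between Mig and RE, 0.27, 0.13 and 0.34 between Mig and RE+GM, 0.09, 0.09 and 0.5 between Mig+GM and RE, 0.32, 0.22 and 0.43 between Mig+GM and RE+GM, and 0.16, 0.32 and 0.33 between RE and RE+GM (numbers 1, 2 and 3). Arrays with other numbers correlated by -0.32 on average between Mig and Mig+GM and by -0.11 to -0.16 between the other groups. The numbers thus paired the Mig with the Mig+GM arrays clearly and the others more weakly, since Mig+GM replicate 2 correlated more with RE replicate 1 (0.26) than with RE replicate 2 and Mig replicate 2 equally with both (0.12). The model had been fixed without a block since the labels do not say what a number shares, and the replicate number as a block is given as an alternative beside each result whose call it changed.

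Gene lists were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 24 lists of at least 5 measured genes within each contrast; camera compares a list's genes with all others. An estimated correlation and fry were alternatives, and fry asks whether a list's genes move one way on balance without comparing them with other genes. The lists, written from general knowledge, were MYC-induced and MYC-repressed genes, STAT5 targets, ERK feedback genes, and genes described as repressed or induced by RUNX1-ETO. They were joined by markers of neutrophils, monocytes and macrophages, dendritic cells, mast cells and basophils, eosinophils, megakaryocytes, erythroid cells, stem cells and lymphoid cells. Others were genes of the cell cycle, DNA repair, p53, interferon, cytokines, cholesterol synthesis, glycolysis together with hypoxia, ribosomal proteins and stress. Lists share some genes, such as Bst2 and Cdkn1a. A count adjusted over the list alone uses only the p-values of that list.

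The groups, contrasts, tests, lists, alternatives and rule for named genes were fixed before the data were examined. By that rule the text names the 8 largest rises and 8 largest falls among called genes of each 2-group contrast (5 each for the interaction), up to 4 members with the smallest p of each list described, and in every contrast Runx1, Runx1t1, Myc, Cd34, Cish and the cytokine receptor genes measured. Alternatives were the replicate block, quantile normalization of log2(signal + 16) without background correction, median scaling, the authors' normalized values, no filter and a strict filter on dim probes (p under 0.01 on all 12 arrays), every probe on its own, only the 2 groups of a contrast, array weights, an intensity trend with robust variance, a minimum fold change of 1.5, and leaving out each array. One more, leaving out all 4 arrays numbered 1, was added after the data had been seen.

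The steps were tested on simulated data with known changes in 50 genes at each size over 12122 genes: for GM-CSF in Mig cells 72% of genes changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold or 8-fold were called, and 5.24% of calls were unchanged genes. For GM-CSF in RE cells the values were 64%, 88%, 98% and 98%, with 2.63%. These simulated data held 230 changed genes for each contrast, with errors independent between arrays. Relations between contrasts were set beside 100 simulations of unchanged groups with independent errors. Added after the data had been seen were the values expected from errors shared by replicate number, whose size came from the residuals, the simulated share of opposite signs and the bounds for the interaction. That simulation kept the observed Mig and RE means, whose own error it counts as effect, and called 5349 units on average (5337 with shared errors). Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.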

Results

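The arrays measured messenger RNA in mouse bone marrow progenitors that carried either an empty retroviral vector (Mig, the control) or the same vector with RUNX1-ETO (RE). RUNX1-ETO is the fusion transcription factor made by a recurrent chromosomal translocation of acute myeloid leukaemia, and GM-CSF is a growth factor of granulocytes and macrophages. Each kind of cell was studied without and with 10 ng/mL GM-CSF for 24 h, after which cells with the vector's green fluorescence, c-Kit on their surface and no mature lineage markers were sorted. The 4 groups (Mig, Mig+GM, RE and RE+GM) held 3 arrays each, 12 in all. The number of arrays limits the precision of every value, and the labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

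The mean deposited signal of the arrays was 597, 431 and 449 in Mig, 411, 440 and 410 in Mig+GM, 318, 338 and 430 in RE, and 459, 457 and 418 in RE+GM, for replicates 1, 2 and 3. Over groups these gave 492 ± 90.9 for Mig, 420.0 ± 17.0 for Mig+GM, 362 ± 59.5 for RE and 445 ± 23.4 for RE+GM (SD, n = 3). The share of probes above background ran from 49.5% on RE replicate 1 to 62.7% on RE replicate 3. Correlations between replicates, across genes, lay between 0.972 (RE replicates 1 and 3) and 0.994. The first principal component held 74.2% of the variance and parted the Mig from the RE arrays, and the next 2 held 9.03% and 5.67%. On the last of these Mig+GM replicate 1 lay apart (-27.4, the other arrays -9.6 to 13.9). In all, 12122 units were tested, 11142 named genes and 980 probes with no gene name.

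The effect of RUNX1-ETO was read first in cells without GM-CSF. RE cells expressed genes of the interferon response far above control cells. Isg15, a ubiquitin-like protein made on interferon exposure, was 77.2-fold higher (log2 6.27, SE 0.24, n = 3 per group, limma adjusted p = 1.04e-08), and Ifi27l2a was 61.5-fold and Rsad2, an antiviral enzyme, 39.7-fold higher. The chemokines Ccl7 and Ccl2, which attract monocytes, were 56.1-fold and 33.5-fold higher (log2 5.81 and 5.07, SE 0.35 and 0.28), with Ccl7 above background on 2 of the 3 Mig arrays and Ccl2 on 1. The largest falls were those of Fcer1g, Prss34 and Tfrc. Fcer1g, the signalling chain of Fc receptors, fell by 3.09 on the log2 scale (SE 0.48, adjusted p = 0.000327), the basophil protease gene Prss34 by 3.06 (SE 0.46) and the transferrin receptor gene Tfrc by 2.98 (SE 0.17, adjusted p = 1.97e-07).

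Ifit3 (5.66), Oasl2 (5.57) and Gbp2 (5.39) completed the 8 largest rises on the log2 scale, and these 3 belong to the interferon response. The other large falls were those of Aqp1 (-2.73), Tspan32 (-2.73), Scin (-2.53), Ces2g (-2.49) and Phlda2 (-2.44). In all 16 of these genes the 3 RE arrays lay on one side of all 3 Mig arrays. That held for 96.8% of the units called by limma, so it adds no support beyond the calls. With limma, 4568 of 12122 units passed an adjusted p of 0.05, 2128 higher and 2440 lower in RE cells, and 1200 of them changed at least 2-fold. Over all 12122 units the groups did not overlap in 45.7%, where chance gives 10% for 3 against 3 unpaired arrays. When arrays were scaled to one median in place of quantiles, 1235 units were called higher and 3457 lower, and a minimum fold change of 1.5 left 2857.

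**Figure D1:**
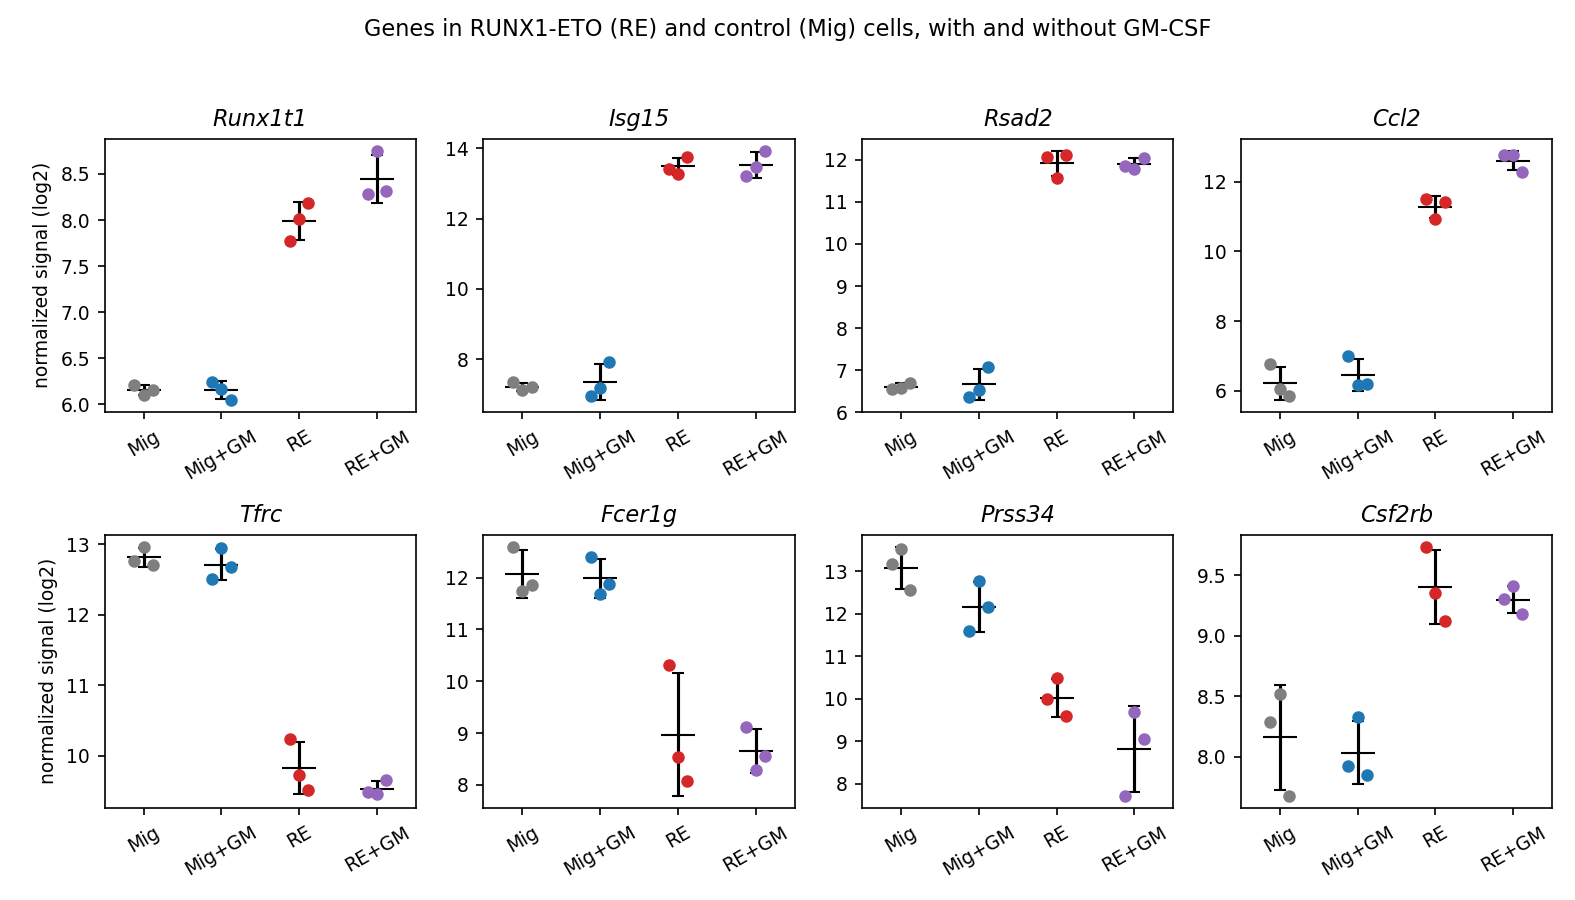
Normalized log2 signal (vertical axes, which do not start at 0) of 8 genes on each array (points) in the Mig, Mig+GM, RE and RE+GM groups, with the group mean (horizontal bar) and SD (vertical bar, n = 3). Runx1t1, Isg15, Rsad2, Ccl2 and Csf2rb lay higher on the RE arrays than on every Mig array, and Tfrc, Fcer1g and Prss34 lay lower.

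The genes of the perturbation and of the cytokine receptors followed. Runx1t1, the gene of the ETO part of the fusion, was at least 3.36-fold higher (adjusted p = 1.59e-06) at its brightest probe (ILMN_2662450), which was above background on 0 of 6 control arrays and on all 6 RE and RE+GM arrays. Its other probe did not rise. Runx1 rose by 0.73 (SE 0.16, adjusted p = 0.00406), a call lost under median scaling (0.31, adjusted p = 0.41, range over alternatives 0.00108 to 0.41). Csf2rb, the gene of the beta chain shared by the GM-CSF, IL-3 and IL-5 receptors, rose by 1.24 (SE 0.22). This was its brightest probe, and its other 2 were not called (0.58, adjusted p = 0.173, and 0.26, adjusted p = 0.109). Csf2rb2, the gene of a beta chain of the IL-3 receptor alone, rose by 1.57 (SE 0.32). The IL-3 receptor gene Il3ra rose by 0.69 (SE 0.13, adjusted p = 0.001), lost under median scaling (0.42, adjusted p = 0.112, the highest of its alternatives, whose lowest was 0.000114). Csf2ra, the GM-CSF-specific chain, differed by 0.80 (adjusted p = 0.0648; 0.00855 with the replicate number as a block, range 0.00457 to 0.253) and was not called. The progenitor marker Cd34 rose by 1.96 (SE 0.11). Myc fell by 0.57 (SE 0.19, adjusted p = 0.0288), and that call ended in 5 alternatives, the authors' own normalization among them (adjusted p = 0.0843, range 0.00172 to 0.113).

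Signalling and inflammatory genes were higher in RE cells. Among 39 interferon-stimulated genes 37 rose, 0 fell and 2 were not called, with 37 rises when adjusted over the list alone. Their median change was 2.39, or 2.30 with genes under background set at their bound (camera adjusted p = 5.86e-30). Oasl1 (4.70, SE 0.10, above background on 2 of 3 Mig arrays) and Gbp3 (3.98) were members. The 34 chemokine, cytokine and NF-kB genes had 18 rises, 4 falls and 12 not called (19 and 4 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 7.62e-05, adjusted p = 0.221 with an estimated correlation). Cxcl10 rose by 3.77, from a level above background on 1 of 3 Mig arrays, and Ccl6 fell by 2.21. Immediate-early and feedback genes of the ERK pathway rose in 10 of 18 cases, fell in 1 and were not called in 7 (10 and 1 adjusted over the list alone, median 0.60, camera adjusted p = 0.000831, adjusted p = 0.194 with an estimated correlation). The phosphatase gene Dusp2 (4.35), Junb (2.30) and Phlda1 (2.83) led them. Of 16 STAT5 target genes 6 rose, 2 fell and 8 were not called (9 and 2 adjusted over the list alone, median 0.39, camera adjusted p = 0.0194, adjusted p = 0.239 with an estimated correlation). Their members Socs3, Socs2 and Cish, feedback inhibitors of cytokine receptors, rose by 1.97, 1.71 and 1.27.

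Genes of growth and division were lower. Of 38 MYC-induced genes 0 rose, 33 fell and 5 were not called, and adjusted over the list alone 1 rose and 35 fell (median -0.90, camera adjusted p = 9.16e-12, adjusted p = 0.194 with an estimated correlation). The nucleotide kinase gene Nme1 (-0.91), Nop58 (-0.91), Ran (-1.02) and Tfdp1 (-1.25) had the smallest p. The 30 genes described as repressed by MYC went the other way, with 19 rises, 2 falls and 9 not called (22 and 3 adjusted over the list alone, median 0.70, camera adjusted p = 3.35e-07). Ddit3 (2.66), H2-D1 (2.15), Hbp1 (2.10) and B2m (1.14) were examples, and of these H2-D1 and B2m encode parts of class I histocompatibility molecules. Of 40 S phase and mitotic genes 0 rose, 35 fell and 5 were not called, with 1 rise and 37 falls adjusted over the list alone (median -0.90, camera adjusted p = 1.07e-13). The replication helicase genes Mcm4 (-1.15) and Mcm5 (-1.21), Kif11 (-1.20) and Birc5 (-1.28) were among the falls. DNA repair genes fell in 19 of 31 cases, with 0 rises and 12 not called (0 and 20 adjusted over the list alone, median -0.52, camera adjusted p = 3.48e-05, adjusted p = 0.221 with an estimated correlation). Msh6 (-1.72) and Apex1 (-1.37) were among them. Cholesterol synthesis genes had 0 rises, 13 falls and 8 of 21 not called (0 and 14 adjusted over the list alone, median -0.60, camera adjusted p = 0.000179, adjusted p = 0.0719 with an estimated correlation), including Lss (-1.38) and Dhcr7 (-1.01).

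Markers of blood cell types moved both ways. The 28 genes of stem and primitive progenitor cells had 14 rises, 2 falls and 12 not called (14 and 3 adjusted over the list alone, median 0.35, or 0.32 with genes under background at their bound, camera adjusted p = 0.000109, adjusted p = 0.0719 with an estimated correlation). Esam (3.71), Egfl7 (2.99) and Eng (2.88) rose, genes that endothelium expresses as well. Of 27 monocyte and macrophage genes 13 rose, 2 fell and 12 were not called (14 and 2 adjusted over the list alone, median 1.01, camera adjusted p = 0.00368, adjusted p = 0.602 with an estimated correlation). Adgre1 (2.17) and Fcgr3 (2.09) rose while Cx3cr1 (-1.09) and Fcer1g fell. Dendritic cell genes rose in 6 of 24 cases, with 0 falls and 18 not called (4 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 0.032, adjusted p = 0.631 with an estimated correlation). The 21 mast cell and basophil genes had 10 rises, 4 falls and 7 not called (11 and 4 adjusted over the list alone, median 0.62, or 0.51 with genes under background at their bound, camera adjusted p = 0.0418, adjusted p = 0.323 with an estimated correlation). Within that list the mast cell protease gene Cpa3 (2.04) and Rgs1 (3.26) rose where Prss34 fell. Erythroid genes had 3 rises, 14 falls and 9 of 26 not called (3 and 16 adjusted over the list alone, median -0.78, camera adjusted p = 0.00121, adjusted p = 0.485 with an estimated correlation). Tfrc, the water channel gene Aqp1, Ermap (-1.50) and Ank1 (-0.84) were lower.

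The other 10 lists did not pass. Genes described elsewhere as repressed by RUNX1-ETO had 3 rises, 8 falls and 11 of 22 not called (3 and 9 adjusted over the list alone, median -0.45, camera adjusted p = 0.217), with Cebpa (-0.90) and Lat2 (-1.09) lower and Gfi1 (3.06) higher. Those described as induced by it had 7 rises, 4 falls and 4 of 15 not called (8 and 4 adjusted over the list alone, median 0.70, camera adjusted p = 0.153), Usp18 (4.77) higher and Alox5 (-2.27) and Bcl2 (-1.32) lower. Neutrophil genes split into 4 rises, 4 falls and 18 not called (3 and 4 adjusted over the list alone, -0.29, camera adjusted p = 0.891). Only 1 of 8 eosinophil genes fell, 0 rose and 7 were not called (0 and 1 adjusted over the list alone, -0.15, camera adjusted p = 0.725). Megakaryocyte genes had 2 rises, 7 falls and 10 not called (2 and 7 adjusted over the list alone, -0.58, camera adjusted p = 0.119). Lymphoid genes had 6, 2 and 10 (6 and 3 adjusted over the list alone, 0.05, camera adjusted p = 0.273), Ccl5 (4.77) among the rises. The counts were 7, 8 and 10 for p53 targets (8 and 9 adjusted over the list alone, median -0.01 but mean 0.08 and test upward, camera adjusted p = 0.803). They were 0, 8 and 19 for ribosomal proteins (0 and 7 adjusted over the list alone, -0.12, camera adjusted p = 0.119). Stress response genes had 7, 6 and 14 (7 and 6 adjusted over the list alone, 0.04, camera adjusted p = 0.624). Glycolysis and hypoxia genes had 4, 3 and 20 (2 and 2 adjusted over the list alone, 0.03, camera adjusted p = 0.614). Among them were Aldoa (0.33) and Gapdh (0.26), which turned to -0.14 and -0.09 under median scaling.

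Camera with its preset correlation thus passed 14 of 24 lists, 9 up and 5 down. With an estimated correlation 3 held, the interferon list (adjusted p = 0.0149), the cell cycle list (adjusted p = 0.0149) and the MYC-repressed list (adjusted p = 0.0164). With the replicate number as a block too, the MYC-repressed list did not pass (adjusted p = 0.0655), and the cholesterol synthesis list did, beside the interferon and cell cycle lists (adjusted p = 0.038 for each of the 3). The estimated correlation gave the highest p of all alternatives for 13 of these 14 lists; the other, the mast cell and basophil list, ranged from 0.00198 to 0.335. The lowest p of each of the 14 lay between 1.73e-37 and 0.00198. Leaving out single arrays ended 2 of the 14 calls, those of the dendritic cell list (adjusted p up to 0.179, without Mig replicate 2) and the mast cell and basophil list (up to 0.0657, without RE replicate 3).

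**Figure D2:**
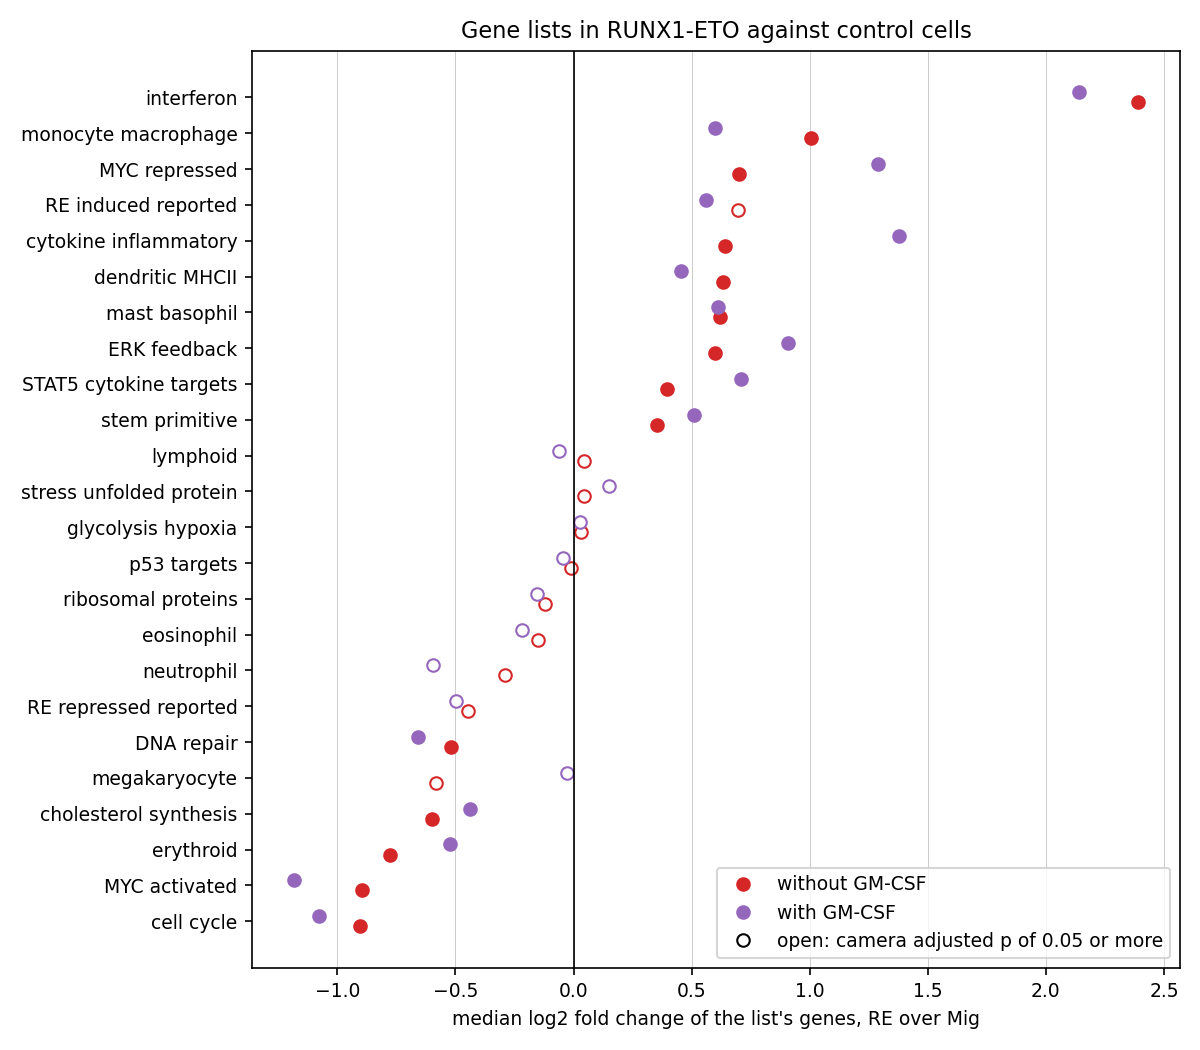
Median log2 fold change, RE over Mig, of the measured genes of each of 24 lists (horizontal axis), without (red) and with (purple) GM-CSF; open circles mark lists whose camera adjusted p was 0.05 or more. The interferon list lay highest, at 2.39 and 2.14, and the cell cycle and MYC-induced lists lowest.

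The same comparison was then made between cells that had received GM-CSF. Chemokine genes were again among the largest rises. Ccl7 was 115-fold higher in RE+GM than in Mig+GM cells (log2 6.84, SE 0.35, n = 3 per group, limma adjusted p = 8.12e-08; above background on 2 of 3 Mig+GM arrays). Ccl2 was 71.5-fold and Ccl12 65.8-fold higher, from levels above background on 1 and 2 Mig+GM arrays. The collagenase gene Mmp13 rose by 5.58 (SE 0.38) and Cd59a, a complement inhibitor, by 5.37 (SE 0.19), beside Isg15 (6.19), Ifi27l2a (5.87) and Gbp2 (5.72). Prss34 (-3.35), Fcer1g (-3.33) and Tfrc (-3.17) again fell most, followed by Sema4a (-2.73), the granulocyte precursor gene Ms4a3 (-2.64), Ifitm1 (-2.56), Tspan32 (-2.48) and the leukotriene enzyme gene Alox5 (-2.47).

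In each of these 16 genes the RE+GM arrays lay wholly on one side of the Mig+GM arrays, as in 98.4% of all called units. Limma called 5101 units, 2275 higher and 2826 lower, of which 1614 changed at least 2-fold. Over all units 52.4% had groups without overlap, against 10% by chance. A minimum fold change of 1.5 left 3384. Of the genes called without GM-CSF, 1724 higher ones were higher here too and 2061 lower ones lower, where 399.4 and 568.8 would be shared by independent lists, and 0 and 5 had opposite calls. Across the 12122 units, which are not independent replicates, the correlation of the RUNX1-ETO effects without and with GM-CSF was 0.907 (jackknife spread over arrays 0.052); the 2 effects share no array. Simulated unchanged groups gave 0.003, and errors shared by arrays of the same replicate number would give 0.303.

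The fusion and receptor genes kept their directions. The Runx1t1 probe was at least 4.57-fold higher. Runx1 rose by 0.88, Csf2rb by 1.26, Csf2rb2 by 1.80, Il3ra by 1.05, Cd34 by 1.45 and Cish by 1.19, and Myc fell by 0.69 (adjusted p = 0.00948). Csf2ra, at 0.36, was not called (adjusted p = 0.403). Several genes were under background on all Mig+GM arrays, which gives lower bounds only: Cxcl2, a neutrophil-attracting chemokine, was at least 29.6-fold higher in RE+GM cells, Cav1 at least 8.11-fold, Slamf1, a stem cell surface receptor, at least 5.17-fold, and Rprm at least 4.6-fold.

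The list counts in this comparison, as rises, falls and genes not called, were 36, 0 and 3 for interferon-stimulated genes (36 and 0 adjusted over the list alone, median 2.14, camera adjusted p = 5.72e-25). For chemokine, cytokine and NF-kB genes they were 23, 4 and 7 (24 and 4 adjusted over the list alone, 1.38, camera adjusted p = 1.12e-07, adjusted p = 0.128 with an estimated correlation). ERK pathway genes gave 11, 0 and 7 (11 and 0 adjusted over the list alone, 0.91, camera adjusted p = 0.000383, adjusted p = 0.136 with an estimated correlation), with Dusp2 at 4.66. STAT5 targets gave 8, 2 and 6 (8 and 2 adjusted over the list alone, 0.71, camera adjusted p = 0.0093, adjusted p = 0.147 with an estimated correlation), with Socs2 at 2.25. MYC-induced genes gave 1, 34 and 3 (1 and 35 adjusted over the list alone, -1.18, camera adjusted p = 2.05e-13, adjusted p = 0.128 with an estimated correlation), with the folate carrier gene Slc19a1 at -1.96. Genes described as repressed by MYC gave 23, 1 and 6 (23 and 2 adjusted over the list alone, 1.29, or 1.22 with genes under background at their bound, camera adjusted p = 1.48e-09), with the cell cycle inhibitor gene Cdkn2b at 2.44. Cell cycle genes gave 0, 35 and 5 (0 and 37 adjusted over the list alone, -1.08, camera adjusted p = 3.35e-13), with the replication licensing gene Cdt1 at -1.52. DNA repair genes gave 1, 21 and 9 (1 and 22 adjusted over the list alone, -0.66, or -0.64 with genes under background at their bound, camera adjusted p = 1.89e-06, adjusted p = 0.136 with an estimated correlation). Cholesterol synthesis genes gave 0, 11 and 10 (0 and 11 adjusted over the list alone, -0.44, camera adjusted p = 0.00307, adjusted p = 0.128 with an estimated correlation), with Lss at -1.63.

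Among cell type markers under GM-CSF, stem and progenitor genes gave 14 rises, 3 falls and 11 not called (15 and 3 adjusted over the list alone, median 0.51, camera adjusted p = 6.19e-05, adjusted p = 0.0757 with an estimated correlation). Mast cell and basophil genes gave 12, 3 and 6 (12 and 3 adjusted over the list alone, 0.61, or 0.36 with genes under background at their bound, camera adjusted p = 0.00396, adjusted p = 0.138 with an estimated correlation), with the histamine-forming enzyme gene Hdc at 2.15. Monocyte and macrophage genes gave 8, 2 and 17 (8 and 2 adjusted over the list alone, 0.60, camera adjusted p = 0.0276, adjusted p = 0.676 with an estimated correlation). Dendritic cell genes gave 6, 1 and 17 (5 and 1 adjusted over the list alone, 0.46, or 0.42 with genes under background at their bound, camera adjusted p = 0.0482, adjusted p = 0.679 with an estimated correlation). Erythroid genes gave 3, 12 and 11 (3 and 13 adjusted over the list alone, -0.52, camera adjusted p = 0.0431, adjusted p = 0.676 with an estimated correlation), with the transcription factor gene Nfe2 at -2.10. Genes described as induced by RUNX1-ETO gave 8, 4 and 3 (8 and 4 adjusted over the list alone, 0.56, camera adjusted p = 0.0376, adjusted p = 0.136 with an estimated correlation).

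The remaining lists, 9 in number, did not pass. Ribosomal protein genes gave 0, 7 and 20 (0 and 6 adjusted over the list alone, -0.15, camera adjusted p = 0.0541, 0.0468 with the replicate block). Genes described as repressed by RUNX1-ETO gave 2, 10 and 10 (2 and 11 adjusted over the list alone, -0.50, camera adjusted p = 0.0775). Neutrophil genes gave 5, 6 and 15 (5 and 6 adjusted over the list alone, -0.59, camera adjusted p = 0.719), and stress response genes 6, 6 and 15 (7 and 7 adjusted over the list alone, 0.15, camera adjusted p = 0.326). Glycolysis and hypoxia genes gave 5, 3 and 19 (4 and 3 adjusted over the list alone, 0.03, camera adjusted p = 0.69). In 4 lists the median was below 0 while the test pointed up. These were megakaryocyte genes (6, 5 and 8, with 6 and 5 adjusted over the list alone, median -0.03, mean 0.17, camera adjusted p = 0.577) and lymphoid genes (5, 3 and 10, with 5 and 3 adjusted over the list alone, -0.06, mean 0.25, camera adjusted p = 0.514). So were p53 targets (8, 8 and 9, with 8 and 9 adjusted over the list alone, -0.04, mean 0.13, camera adjusted p = 0.725) and eosinophil genes (1, 0 and 7, with 1 and 0 adjusted over the list alone, -0.22, mean -0.15, camera adjusted p = 0.85). In all, 15 of 24 lists passed, 10 up and 5 down. Those that held with an estimated correlation were again the interferon, cell cycle and MYC-repressed lists (adjusted p = 0.0117 for each). With the replicate number as a block too, the cholesterol synthesis and the stem and progenitor list passed beside these 3 (adjusted p = 0.0436 for each of the 5). The estimated correlation alone gave the highest p of all alternatives in 14 of the 15; the list of genes described as induced by RUNX1-ETO ranged from 1.26e-05 to 0.147. The lowest p of each of the 15 lay between 2.9e-32 and 0.00118. Leaving out single arrays ended 4 of the 15 calls, those of the dendritic cell (adjusted p up to 0.3), erythroid (up to 0.104), monocyte (up to 0.102) and RUNX1-ETO-induced (up to 0.0593) lists.

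GM-CSF on its own gave few calls in control cells. Bcat1, an enzyme of branched-chain amino acid metabolism, rose 2.98-fold (log2 1.57, SE 0.19, n = 3 per group, limma adjusted p = 0.0392; higher on all 3 Mig+GM arrays than on any Mig array). It was the single unit called of 12122, with 643 at an unadjusted p under 0.05 (1004 with the replicate block) and 0 called lower. Over all units 9.78% had groups without overlap, against 10% by chance for unpaired arrays. The Mig and Mig+GM arrays were paired by number, so the 10% does not apply to them. The 9.78% therefore does not show that there was no effect. The main model ignores this pairing, and the replicate block fits 1 shift per number alike in all groups. A paired test within Mig cells alone was not run. Limma was the only tool run per gene. Batf3, a transcription factor of dendritic cells, differed by 1.56 (adjusted p = 0.429, 0.0388 with the replicate block, which called 2 units, range over alternatives 0.0388 to 1). The STAT5 target Cish differed by 0.78 (SE 0.17, adjusted p = 0.429), and none of Runx1t1, Runx1, Myc, Cd34, Csf2rb, Csf2rb2, Csf2ra and Il3ra was called.

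The Bcat1 call rested on the arrays used, and its adjusted p ranged from 0.00904 to 0.804 over alternatives. By limma 0 units were called without Mig replicate 1 or 2, without any of the Mig+GM or RE+GM arrays, or without RE replicate 2 or 3, and 1 was called without Mig replicate 3 or RE replicate 1. Its other 2 probes were not called (0.31, adjusted p = 0.783, and 0.14, adjusted p = 0.999). In simulated data of this size limma called 96% of genes changed by 1 on the log2 scale. Those data held 230 changed genes, with errors independent between arrays. Many changed genes ease the adjusted threshold, so the 96% does not show what would be called where few genes changed.

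Camera still passed 13 of the 24 lists in control cells, although 0 members of any list were called. Genes of red cells and platelets lay lower. Erythroid genes had a median of -0.45 (camera adjusted p = 2.9e-11, adjusted p = 0.262 with an estimated correlation) and megakaryocyte genes -0.50 (camera adjusted p = 1.03e-05, adjusted p = 0.262 with an estimated correlation). Lower too were genes of mast cells and basophils (-0.31, camera adjusted p = 0.000598, adjusted p = 0.241 with an estimated correlation), eosinophils (-0.22, camera adjusted p = 0.0342, adjusted p = 0.483 with an estimated correlation) and the cell cycle (-0.09, camera adjusted p = 0.0211, adjusted p = 0.358 with an estimated correlation). STAT5 targets lay higher, at 0.28 (camera adjusted p = 3.31e-06, adjusted p = 0.0721 with an estimated correlation), with Cish and Pim3 (0.64) as members. Stress response genes lay higher too (0.14, camera adjusted p = 0.000598, adjusted p = 0.0688 with an estimated correlation). So did glycolysis and hypoxia genes (0.16, camera adjusted p = 0.000752, adjusted p = 0.358 with an estimated correlation). ERK pathway genes (0.14, camera adjusted p = 0.00414, adjusted p = 0.309 with an estimated correlation) and dendritic cell genes (0.22, camera adjusted p = 0.00557, adjusted p = 0.611 with an estimated correlation) followed. Interferon-stimulated genes (0.09, camera adjusted p = 0.0266, adjusted p = 0.483 with an estimated correlation), cholesterol synthesis genes (0.10, camera adjusted p = 0.0266, adjusted p = 0.309 with an estimated correlation) and MYC-induced genes (0.05, camera adjusted p = 0.0367, adjusted p = 0.666 with an estimated correlation) completed the 13. The last had its sign turned under median scaling and without Mig replicate 1.

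In these control cells 0 lists held with an estimated correlation and 0 with fry. Over the 13 lists the lowest p of any alternative lay between 5.34e-13 and 0.00533 and the highest between 0.0949 and 0.899. Leaving out single arrays ended 7 of the 13 calls. The dendritic cell list had an adjusted p of 0.888 without Mig+GM replicate 1, the array apart on the third component, and of 1.02e-11 without Mig replicate 1. The eosinophil list reached 0.894 and the MYC-induced list 0.899 without Mig+GM replicate 2, the interferon list 0.521 and the ERK list 0.0975 without Mig+GM replicate 3, the cell cycle list 0.211 without Mig+GM replicate 1 and the cholesterol synthesis list 0.232 without Mig replicate 3. Adjusted over the list alone, 3 STAT5 targets, 2 stress response genes, 1 dendritic and 1 monocyte gene were higher, and 3 erythroid genes, 3 mast cell and basophil genes, 1 stem cell gene and 1 gene described as repressed by RUNX1-ETO were lower, with 0 in every other list. For stem cell genes (median 0.01, mean -0.02, test downward, camera adjusted p = 0.97) and ribosomal protein genes (0.03, mean -0.005, test upward, camera adjusted p = 0.97) median, mean and test differed in sign.

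The effect of GM-CSF in RE cells was read next, from the 8 largest rises and falls. Ppbp, a platelet chemokine, rose 19.6-fold (log2 4.29, SE 0.46, n = 3 per group, limma adjusted p = 0.000901). The neuropeptide genes Grp and Nts rose by 4.26 (SE 0.25, adjusted p = 8.63e-06; above background on 2 of 3 RE arrays) and 3.75 (SE 0.46). The other Nts probe was not called (0.33, adjusted p = 0.165). The carbonic anhydrase gene Car4 rose by 3.68 (SE 0.20), the protease inhibitor genes Cstdc4 and Csta2 by 3.49 and 3.12, Irx3 by 3.04 and the T cell chemokine gene Ccl17 by 3.00 (SE 0.36). Falls were smaller, led by Adamtsl4 (-1.34, SE 0.25, adjusted p = 0.0159), Eng, a receptor of the TGF-beta family (-0.89), and Slc4a8 (-0.84). Angptl4 (-0.76), Nisch (-0.75), Cd1d1 (-0.75), Art5 (-0.70) and Zfp35 (-0.67) followed. The Angptl4 call (adjusted p = 0.0467, range over alternatives 0.00404 to 0.219) was lost in 16 of 24 alternatives, that of Slc4a8 in 10 and those of Eng, Nisch and Zfp35 in 9 each.

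The RE+GM arrays lay wholly to one side of the RE arrays in all 16 of these genes. They did so in 100% of the called units, so this adds no support beyond the calls. Over all units 22.8% had groups without overlap, against 10% by chance. Limma called 273 units, of which 229 were higher and 44 lower, and 97 changed at least 2-fold. Of all units, 2181 had an unadjusted p under 0.05. With the replicate number as a block 703 were called (407 higher, 296 lower). Single arrays mattered: 150 units were called without RE replicate 1, 118 without RE replicate 2, 910 without RE replicate 3, and 150, 102 and 164 without RE+GM replicates 1, 2 and 3.

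**Figure D3:**
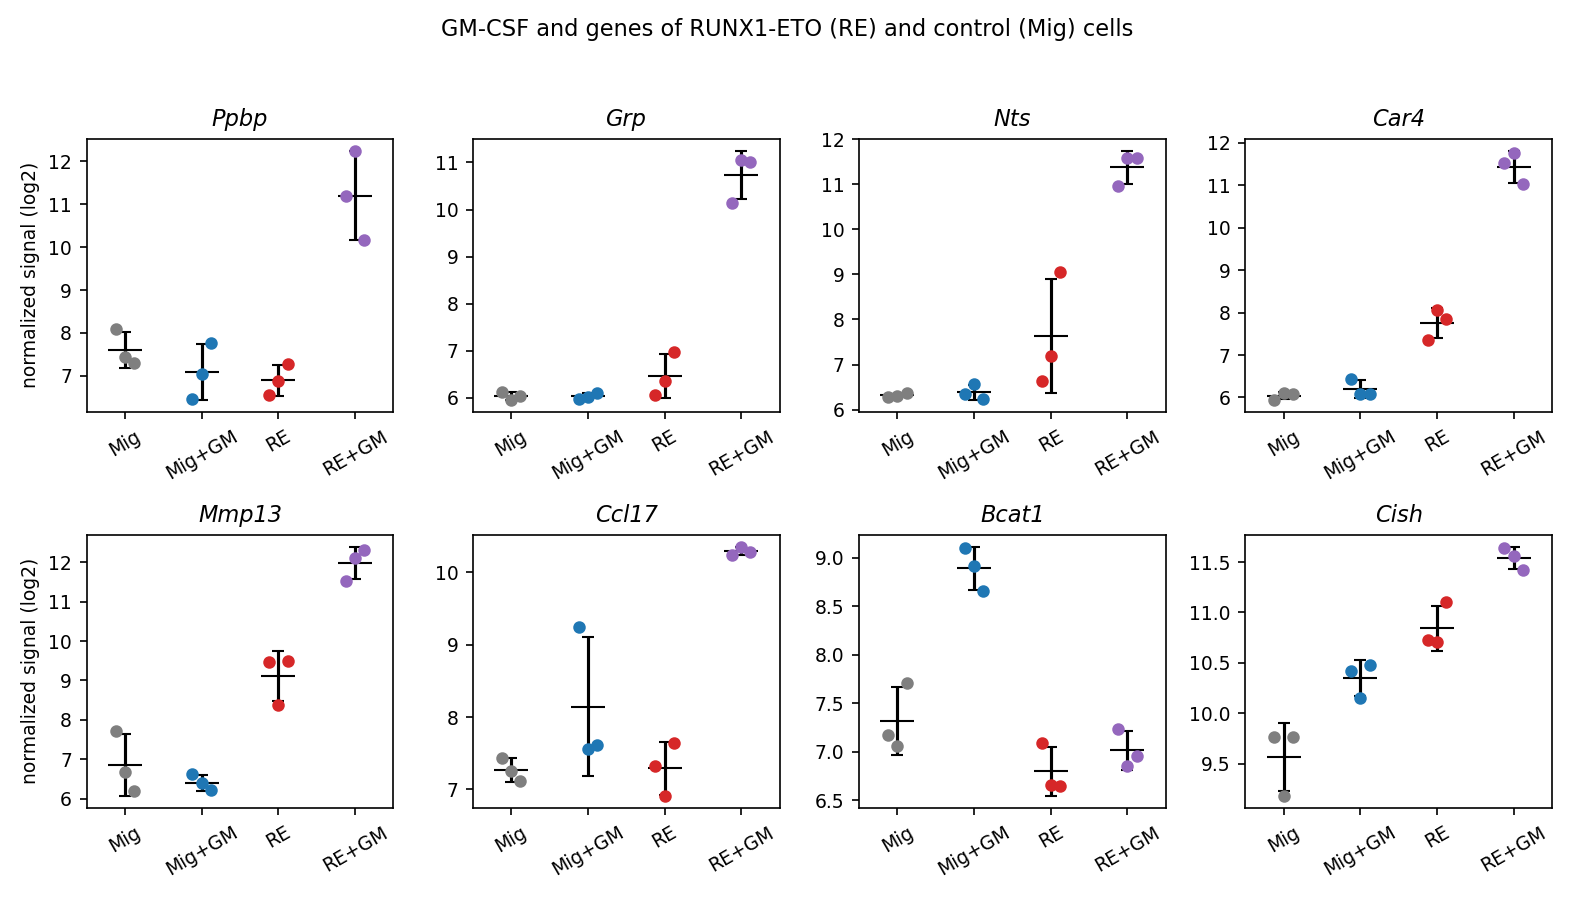
Normalized log2 signal (vertical axes, which do not start at 0) of 8 genes on each array (points) in the 4 groups, with the group mean (horizontal bar) and SD (vertical bar, n = 3). Ppbp, Grp, Nts, Car4, Mmp13 and Ccl17 lay highest on the RE+GM arrays, Bcat1 lay highest on the Mig+GM arrays, and Cish lay higher with GM-CSF in both kinds of cell without passing the test.

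Chemokine, cytokine and NF-kB genes had 10 rises, 0 falls and 24 not called with GM-CSF in RE cells (13 and 0 adjusted over the list alone, median 0.19, mean 0.68, camera adjusted p = 5.9e-08, adjusted p = 0.118 with an estimated correlation). The neutrophil-attracting chemokine genes Cxcl1 (2.99, SE 0.39, adjusted p = 0.00229) and Cxcl2 (2.73) and the NF-kB cofactor gene Nfkbiz (1.17) were among them. Genes described as repressed by MYC had 6, 0 and 24 (8 and 0 adjusted over the list alone, 0.20, camera adjusted p = 1.94e-05, adjusted p = 0.0504 with an estimated correlation). Their rises included Cdkn2b (1.84, adjusted p = 2.27e-05), Mxi1 (1.18), Thbs1 (1.00) and Itgb1 (0.50). STAT5 targets had 3, 0 and 13 (6 and 1 adjusted over the list alone, 0.33, camera adjusted p = 8.72e-05, adjusted p = 0.0792 with an estimated correlation), with Il2ra (1.01), Id1 (0.78) and Pim1 (0.77) called. ERK pathway genes had 1, 0 and 17 (2 and 0 adjusted over the list alone, 0.23, camera adjusted p = 0.000413, adjusted p = 0.152 with an estimated correlation), the call being Ier3 (1.53). Genes described as induced by RUNX1-ETO had 3, 0 and 12 (5 and 0 adjusted over the list alone, 0.10, camera adjusted p = 0.00072, adjusted p = 0.0598 with an estimated correlation), with Cav1 at 2.18. Stress response genes had 0 calls among 27 (1 and 0 adjusted over the list alone, 0.27, camera adjusted p = 0.000218, adjusted p = 0.0504 with an estimated correlation). Cholesterol synthesis genes had 0 calls among 21 and 0 adjusted over the list alone (0.10, camera adjusted p = 0.0067, adjusted p = 0.152 with an estimated correlation). Glycolysis and hypoxia genes had 1 rise, Egln3 (1.19), and 26 not called (1 and 0 adjusted over the list alone, 0.09, camera adjusted p = 0.0328, adjusted p = 0.585 with an estimated correlation).

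The lists of growth and division moved further down on balance in RE cells under GM-CSF. MYC-induced genes had a median of -0.29 (camera adjusted p = 0.00011, adjusted p = 0.44 with an estimated correlation), with 1 rise, Odc1 (0.76), 0 falls and 37 not called (1 and 0 adjusted over the list alone). Cell cycle genes had 0 rises, 1 fall, Mcm5 (-0.54, lost in 12 of 24 alternatives), and 39 not called (0 and 2 adjusted over the list alone, -0.22, camera adjusted p = 0.000218, adjusted p = 0.141 with an estimated correlation). DNA repair genes had 0, 1 and 30 (0 and 6 adjusted over the list alone, -0.19, camera adjusted p = 0.000413, adjusted p = 0.313 with an estimated correlation), the fall being that of the DNA polymerase gene Pold1 (-0.65). These 11 lists passed, 8 up and 3 down, and 0 held with an estimated correlation, which gave the highest p of all alternatives in 10 of the 11; the cell cycle list ranged from 6.54e-05 to 0.143. The lowest p of each lay between 4.82e-12 and 0.0051. Leaving out single arrays ended only the call of the glycolysis and hypoxia list (adjusted p up to 0.532, without RE replicate 1). Fry passed 7 lists, leaving out the ERK list, the MYC-induced list, the cholesterol synthesis list and the glycolysis and hypoxia list.

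Of the lists that did not pass in RE cells, mast cell and basophil genes had 3 rises (Ccl4, 1.81; Ccl3, 1.29; Il13, 0.67), megakaryocyte and p53 target genes 2 each, neutrophil, monocyte and dendritic genes 1 each, and stem cell genes 1 fall, that of Eng. The interferon list had 0 calls (median -0.11, camera adjusted p = 0.0791), as had the erythroid, eosinophil, lymphoid and ribosomal lists and the genes described as repressed by RUNX1-ETO. The interferon list passed in 5 of 24 alternatives (lowest camera adjusted p = 0.00175, without RE+GM replicate 3). Erythroid, dendritic cell, megakaryocyte and p53 lists passed in 3 of 24 each. Signs differed for monocyte genes (median -0.17, mean -0.05, test upward, camera adjusted p = 0.698) and dendritic cell genes (-0.06, mean 0.14, upward, camera adjusted p = 0.23). They also differed for mast cell and basophil genes (-0.06, mean 0.04, upward, camera adjusted p = 0.562) and lymphoid genes (0.02, mean -0.06, upward, camera adjusted p = 0.68). Cish (0.70, adjusted p = 0.0552, 0.0184 with the block, range 0.0118 to 0.43), Socs2 (1.09, 0.0509, 0.0407 with the block, range 0.00154 to 0.291) and Egr2 (0.79, 0.0568, 0.0275 with the block, range 0.00645 to 0.209) were just short of a call. Runx1t1 (0.46, adjusted p = 0.111), Runx1, Myc, Cd34, Il3ra, Csf2ra, Csf2rb and Csf2rb2 were not called.

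Whether GM-CSF moved the genes of RUNX1-ETO back towards control was asked over the 4568 called units, 40.5% of which had the opposite sign under GM-CSF in RE cells. The jackknife spread of that share over arrays was 5.93. Both effects use the RE arrays, whose error favours opposite signs. In simulated data in which RUNX1-ETO kept its effect and GM-CSF had none, 58.9% of called units had opposite signs (SD 0.56, 50 simulations), or 57.8% (SD 0.61) with errors shared by arrays of the same replicate number. Under median scaling the observed share was 53.6%. Of the units higher in RE cells 52.6% moved down with GM-CSF, where the simulations gave 58.4% and 57.5%, and of those lower 29.9% moved up, where they gave 59.2% and 58.1%. Across the 12122 units, not independent replicates, the correlation of the 2 effects was 0.173 and their covariance 0.0361, against a covariance of -0.0213 in simulated unchanged groups that share the RE arrays (-0.0158 from errors shared by replicate number as well). Of the 229 units raised by GM-CSF in RE cells 106 were already higher and 20 lower in RE than in Mig cells, where independent lists would share 40.2 and 46.1.

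The difference between the GM-CSF effects in RE and in Mig cells was tested itself, as an interaction. Ppbp rose by 4.80 more on the log2 scale in RE than in Mig cells (SE 0.66, n = 3 per group, limma adjusted p = 0.0136), Grp by at least 3.66 (adjusted p = 0.000372) and Nts by 3.68 (SE 0.64, adjusted p = 0.0478). Car4 rose by at least 3.14 (adjusted p = 0.000372) and Mmp13 by 3.31 (SE 0.54, adjusted p = 0.0411) more. In all 5 genes every RE+GM array lay above every array of the other groups. Grp was above background on 0 and Car4 on 1 of the 6 Mig and Mig+GM arrays, so that their differences are lower bounds. The calls of Nts (range over alternatives 3.57e-05 to 0.321) and Mmp13 (range 0.00994 to 0.130) were lost in 17 and 11 of 22 alternatives. Among list members Ltb4r1, a leukotriene B4 receptor gene (2.40, lost in 15 of 23 alternatives), Cav1 (at least 2.19, adjusted p = 0.00863) and Cdkn2b (1.90, adjusted p = 0.000785) also passed. Cxcl1 (adjusted p = 0.0563, 0.0298 with the block, range 0.000274 to 0.523) and Cxcl2 (adjusted p = 0.0565, 0.0314 with the block, range 3.57e-05 to 0.523), both under background on all 6 Mig and Mig+GM arrays, did not. Nor did Cish (-0.08, adjusted p = 0.935), Runx1t1 (0.46, adjusted p = 0.486) or Bcat1.

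Limma called 32 units for the interaction, all higher, with 1126 at an unadjusted p under 0.05; the replicate block called 74 (63 higher, 11 lower). Without Mig replicates 1, 2 and 3 it called 8, 11 and 18, and without Mig+GM replicates 1, 2 and 3 it called 20, 16 and 11. Without RE replicates 1, 2 and 3 it called 15, 10 and 189, and without RE+GM replicates 1 and 2 it called 20 and 10. Across units, which are not independent replicates, the GM-CSF effects in RE and Mig cells had a correlation of 0.209 (jackknife spread 0.198). Simulated unchanged groups with independent errors gave -0.001, but errors shared by arrays of the same replicate number would give 0.105, and the observed value lies within its spread of that.

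**Figure D4:**
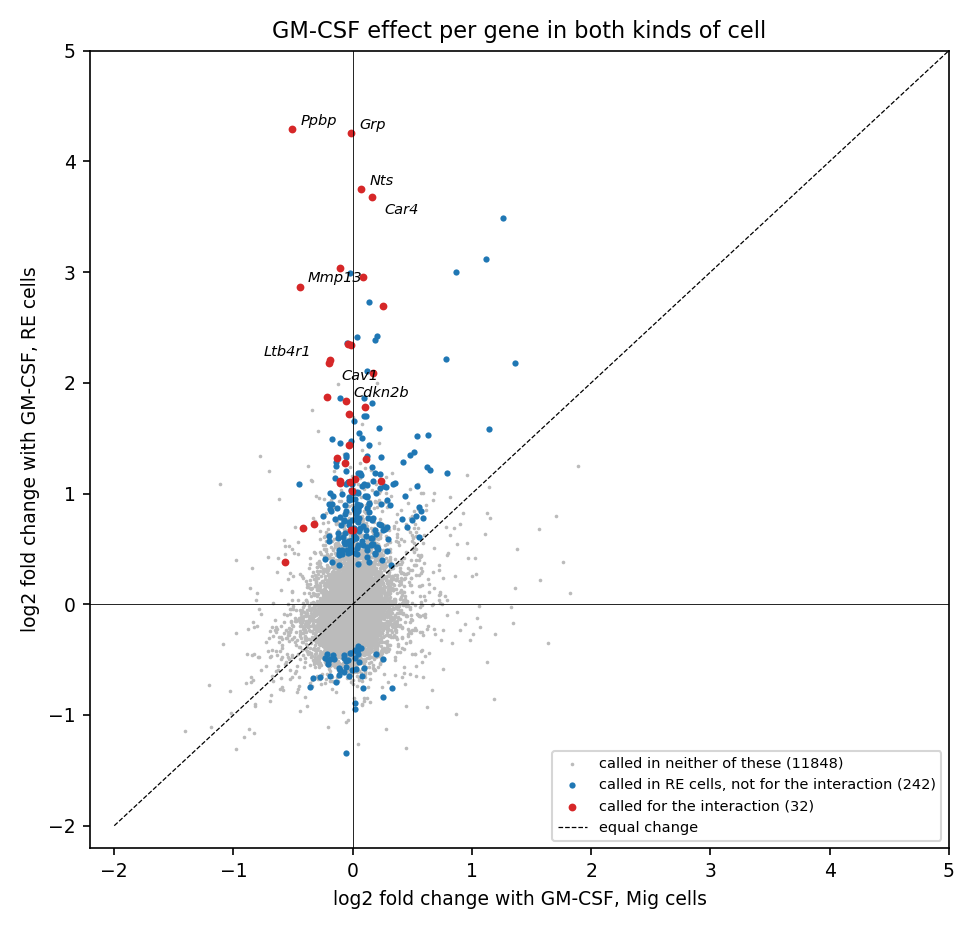
Log2 fold change with GM-CSF of each of the 12122 units in Mig cells (horizontal axis) and in RE cells (vertical axis). Red points mark the 32 units called for the interaction, blue points the 242 called in RE cells but not for the interaction, grey points the other 11848, and the dashed line equal change.

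Camera passed 9 lists for the interaction, 6 up and 3 down. Up here means higher relative to the change in Mig cells, which need not be a rise in RE cells. The megakaryocyte, mast cell and basophil, and erythroid lists had passed downward in Mig cells (medians -0.50, -0.31 and -0.45). In RE cells these lists did not pass (camera adjusted p = 0.109, 0.562 and 0.139). Megakaryocyte genes had a median difference of 0.26 (1 rise, Ppbp, 0 falls, 18 not called; 3 and 0 adjusted over the list alone, camera adjusted p = 2.02e-05, adjusted p = 0.271 with an estimated correlation). Chemokine, cytokine and NF-kB genes had 0.07 with a mean of 0.57 (0 called; 7 and 0 adjusted over the list alone, camera adjusted p = 3.58e-06, adjusted p = 0.271 with an estimated correlation). MYC-repressed genes had 0.15 (1 rise, Cdkn2b; 3 and 0 adjusted over the list alone, camera adjusted p = 0.000144, adjusted p = 0.198 with an estimated correlation). Genes described as induced by RUNX1-ETO had 0.17 (1 rise, Cav1; 1 and 0 adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.271 with an estimated correlation, range 0.0106 to 0.336). Mast cell and basophil genes had 0.46 (0 called; 2 and 0 adjusted over the list alone, camera adjusted p = 0.00366, adjusted p = 0.271 with an estimated correlation). Erythroid genes had 0.24 (0 called; 1 and 0 adjusted over the list alone, camera adjusted p = 0.0115, adjusted p = 0.668 with an estimated correlation, range 0.000249 to 0.681). Lower were MYC-induced genes (-0.32, camera adjusted p = 3.58e-06), DNA repair genes (-0.19, camera adjusted p = 0.00673) and interferon-stimulated genes (-0.17, camera adjusted p = 0.00385), each with 0 calls, 0 adjusted over the list alone and an adjusted p = 0.5 with an estimated correlation. With an estimated correlation or with fry 0 of the 9 held; the former gave the highest p in 7 of them, and the lowest p of each lay between 2.2e-08 and 0.0106. Leaving out single arrays ended 4 of the 9 calls, those of the erythroid (adjusted p up to 0.473), interferon (up to 0.182), RUNX1-ETO-induced (up to 0.0822) and DNA repair (up to 0.0758) lists. Of the other 15 lists the neutrophil list had 1 call, Ltb4r1, and STAT5 targets had a median of -0.03 but a mean of 0.12 and a test upward (camera adjusted p = 0.423). The cell cycle list (camera adjusted p = 0.0527, range 0.0113 to 0.5) passed in 9 of 23 alternatives. The ERK list passed in 3 of 23 and the eosinophil list in 2 of 22. Dendritic cell, monocyte, neutrophil, lymphoid and RUNX1-ETO-repressed lists passed in 1 each.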

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

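The tests of a weaker RUNX1-ETO effect on 1 array, of array brightness, of more RUNX1-ETO under GM-CSF, of endothelial cells and macrophages, the splits that part every pair of arrays, and the values from pairs left out in turn, were chosen only after the results had been seen; the others were planned. Groups of 3 arrays are too small to test for single outlying samples.

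The GM-CSF effect differed between RE and Mig cells in 32 units by limma's interaction test, with larger values in RE cells for Ppbp (4.80 on the log2 scale), Grp (4.27 by the model, at least 3.66 against background), Nts (3.68), Car4 (3.52, at least 3.14), Mmp13 (3.31), Ltb4r1 (2.40), Cav1 (2.38, at least 2.19) and Cdkn2b (1.90). Lists whose camera test differed between the 2 kinds of cell had median differences of 0.46 for mast cell and basophil genes, 0.26 for megakaryocyte, 0.24 for erythroid, 0.17 for genes described as induced by RUNX1-ETO, 0.15 for MYC-repressed and 0.07 for cytokine genes, and of -0.32 for MYC-induced, -0.19 for DNA repair and -0.17 for interferon-stimulated genes. The mast cell and basophil, megakaryocyte and erythroid lists lay lower with GM-CSF in Mig cells and did not pass in RE cells. With an estimated correlation 0 of these 9 lists passed (adjusted p from 0.198 to 0.668). With other splits of the GM-CSF label within Mig and within RE arrays, 10 of 100 gave as many as 32 units, the real one included, and the highest other gave 167. Each split with at least 32 kept the RE arrays parted by GM-CSF, as they are or with RE and RE+GM exchanged. Such splits still set any response of the RE cells against the Mig arrays. The share therefore cannot decide about chance, which is not excluded. All these drawn splits ignore the pairing by replicate number. Of the 32 splits that part every pair, 4 gave at least 32 units (highest other 125), and with the replicate block 2 gave as many as the real 74 (highest other 321, with RE and RE+GM exchanged). In these too the RE arrays stayed parted or exchanged, so they cannot decide about chance either.

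For the 4 comparisons of 2 groups, 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with the most calls in each: 4568 and 5101 for RUNX1-ETO without and with GM-CSF and 1 for GM-CSF in Mig cells, where the highest other split called 0 by limma, and 273 for GM-CSF in RE cells, where the highest other called 2.

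RE replicate 1 stood apart from the other RE arrays, with the lowest mean signal (318) and a correlation of 0.972 with RE replicate 3. A dim array would differ mainly in dim genes, and the difference was not confined to these. Among 1671 genes with a mean over 10 its median difference from RE replicate 3 was 1.54 times that of RE replicate 2 (interval over genes 1.45 to 1.68), where at most 1.2 had been set for a dim array. The ratio was 1.31, 1.53, 1.6 and 1.51 in genes with a mean under 7, from 7 to 8, from 8 to 9 and from 9 to 10, so it was not larger in dimmer genes. The offset makes differences of the dimmest genes smaller, so their ratio says little. The planned bound for arguing against dimness, 1.5, lies inside the interval. The limit of 1.2 was taken to decide only after the values had been seen, so dimness is not excluded. RE replicate 2 was itself dim (338), and a loss of signal alike in all genes was not tested. A weaker RUNX1-ETO effect on that array may also account for it: its slope on the RUNX1-ETO effect under GM-CSF was 0.707, against 0.769 and 0.919 for RE replicates 2 and 3, while its interferon genes lay as high above Mig (2.49 against 2.41 and 2.57). The tested Runx1t1 probe read 7.77, 8.01 and 8.19 on RE replicates 1 to 3, in the order of the slopes and of the mean signals. The second principal component placed these arrays in that order too (33.9, 15.2 and -3.1). They thus lie in a row, with RE replicate 3 at the other end. This explanation stays open too, since a slope at least 0.1 below both others was set to support it and 1 such array is too few.

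GM-CSF called more genes in RE cells (273) than in Mig cells (1). With the replicate block the counts were 703 and 2. The Mig and Mig+GM arrays were paired by number more clearly than the RE and RE+GM arrays, which the main model ignores. The block fits 1 shift per number alike in all groups, and a paired test within Mig cells alone was not run. Lower power in Mig cells is therefore not excluded as a cause of the difference in counts. RE replicate 1 as the sole cause is argued against, since 150 units were called without it, against 118 without RE replicate 2, 910 without RE replicate 3 and 150, 102 and 164 without RE+GM replicates 1, 2 and 3. Brightness was weighed in the pair numbered 3, whose RE and RE+GM arrays are about equally bright (mean signal 430 and 418), where those of the other pairs are not. There the 206 genes called higher without it had a median change of 0.52 (interval over genes 0.46 to 0.62). Of them 94.2% were positive, against 64.1% between the Mig arrays of that number. The same genes changed by 1.18 and 1.13 in the pairs numbered 1 and 2, which also served to choose them. A change, though smaller, was thus seen without that difference in brightness. A value over 0.5 was set to argue against brightness, and 0.5 lies inside the interval. With the pairs numbered 1 and 2 left out instead, the median change in the pair left out was 1.23 over 70 genes and 2.70 over 10, but these are other genes, so the sizes are not comparable. More RUNX1-ETO under GM-CSF may also contribute, since the 229 genes raised had a median RUNX1-ETO effect of 0.41 (195 positive, 85.2%), though interferon-stimulated genes, which RUNX1-ETO raised most, had a median of -0.11 with GM-CSF and Runx1t1 differed by 0.46 (adjusted p = 0.111). Brightness cannot be told apart from a true difference in the response, because it changes with the group in the pairs numbered 1 and 2 and the 1 pair that is left is too few. Nor can the amount of RUNX1-ETO, which was not measured apart from the group.

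Chemokine and matrix genes such as Ccl2, Ccl7 and Mmp13 were high in RE cells, and cells of another type in the sort, which selected fluorescent, c-Kit-positive, lineage-negative cells and should remove them, were weighed as the source. Fibroblasts are argued against: the median change of 11 tested of 22 fibroblast genes on the array was -0.02 without and 0.01 with GM-CSF, and Col1a1, Col3a1, Dcn and Lum were not above background on any RE array, although Sparc (at least 3.71-fold without and 11.6-fold with GM-CSF) and Acta2 (0.94 and 1.51) rose and, with GM-CSF only, Timp3 (1.63) and Col1a2 (0.56, adjusted p = 0.00244, above background on all arrays of every group) did. Col5a1 (-1.52 and -1.14) and Igfbp7 (-1.70 and -1.17) fell, and Thy1 did with GM-CSF (-1.62). Endothelial cells may contribute, with a median of 0.84 without and 0.94 with GM-CSF over 15 tested genes (0.76 and 0.94 with genes under background at their bound). Of these 11 and 10 were higher, among them Emcn (at least 1.69-fold and 1.43-fold), but not Kdr (0.09 and -0.06) or Plvap (-0.09 and -0.16). Cdh5 was called higher in both as well (0.25, limma adjusted p = 0.0182, and at least 1.25-fold, adjusted p = 2.03e-05). It lay near background, above it on 4 RE and RE+GM arrays and on 0 Mig and Mig+GM arrays. Mature macrophages may contribute, with a median of 0.56 without and 0.95 with GM-CSF over 16 tested genes, 7 and 9 of them higher, among them Axl (3.88 and 2.54) and Ctsb (1.05 and 0.97). Apoe rose with GM-CSF (1.55, adjusted p = 1.62e-05) but was not called without it (0.10), and C1qb was not called in either (-0.35 and 0.25), while C1qa (-0.11 and 0.13) was too dim to test. These 2 sources cannot be told apart from expression in the progenitors themselves, which share such genes: 5 endothelial, 3 macrophage and 2 fibroblast genes stand in the other lists too.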

How the results depend on the processing

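Leaving out all 4 arrays numbered 1 was chosen after the data had been seen; the other alternatives were planned, but neqc and the slide as a block could not be run, as no detection p-values or slides are named. Over all named genes 11722 comparisons with an alternative kept direction and side of the threshold, 126 passed newly, 277 no longer passed and 2 turned; for lists the counts were 2609, 68, 170 and 4. A minimum fold change of 1.5 left 2857 and 3384 units for RUNX1-ETO without and with GM-CSF, by construction. For all else here the cause was not tested. With the replicate block 2, 703 and 74 units were called for GM-CSF in Mig cells, in RE cells and for the interaction, 1 list (ribosomal proteins) and 25 calls of named genes were gained, and no other call of a list or named gene changed. For RUNX1-ETO without and with GM-CSF it called 5175 and 5664 units and kept 4545 of 4568 and 5074 of 5101. For GM-CSF in Mig cells limma called 0 under median scaling (1043 at an unadjusted p under 0.05), with the authors' values (623), with every probe (801), with 2 groups (589) and without the arrays numbered 1 (376), and 0 to 1 without single arrays. For GM-CSF in RE cells it called 112 with the strict filter, 116 with 2 groups, 998 with array weights, 72 without the arrays numbered 1, and 102 to 910 without single arrays (RE replicate 1 150, 2 118, 3 910; RE+GM replicate 1 150, 2 102, 3 164). For the interaction it called 12 under median scaling, 2 with the strict filter, 98 with array weights, 49 with a trend, 5 without the arrays numbered 1, and 8 to 189 without single arrays (Mig 8, 11, 18; Mig+GM 20, 16, 11; RE 15, 10, 189; RE+GM 20 and 10 for replicates 1 and 2).

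Lists passing fell with an estimated correlation to 3 of 14 and 3 of 15 for RUNX1-ETO without and with GM-CSF, and to 0 of 13, 0 of 11 and 0 of 9 for GM-CSF in Mig cells, in RE cells and for the interaction; fry passed 0, 7 and 0 of these last 3, and median scaling 4 for the interaction. Median scaling moved the median of all units for the interaction from -0.03 to 0.14, the share of higher calls from 46.6% to 26.3% for RUNX1-ETO without GM-CSF and from 83.9% to 97.5% for GM-CSF in RE cells (68.3% with the authors' values), and the share of opposite signs from 40.5% to 53.6%. It turned Aldoa (-0.14) and Gapdh (-0.09) and, for GM-CSF in Mig cells, the MYC-induced list (adjusted p = 0.696), which also turned without Mig replicate 1 (0.829; 0.000226 to 0.899 over single arrays). Without Mig+GM replicate 1 the neutrophil list (0.00653; range 6e-04 to 0.699) and the monocyte list (0.0322; range 2.2e-07 to 0.916) turned. Signal over background limits what is seen: 49.5% to 62.7% of probes were above it on an array.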

Other observations

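The genes named here were chosen only after their values had been seen, and they come from the marker lists used to weigh other cell types in the sort, which were not tested as sets. Of 15 tested endothelial marker genes 11 were called higher in RE than in Mig cells without GM-CSF and 10 with it (limma), among them Flt1 by 3.05 and 2.18, Ramp2 by 2.90 and 3.52, Pecam1 by 1.48 and 2.59 and Tek by 0.86 and 0.94. Kdr (0.09, adjusted p = 0.352), Robo4 (0.20, adjusted p = 0.367), Plvap and Stab2 were not called. Of 16 tested macrophage marker genes 7 were called higher without and 9 with GM-CSF, among them Lgmn by 2.02 and 2.77, Ctss by 1.98 and 1.56 and Hmox1 by 0.82 and 0.93. Ctsd (0.10, adjusted p = 0.711) and Lyz2 (1.54, adjusted p = 0.129) were not called.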
